A study of Mus musculus with 20 samples.

How the data were processed

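RNA was measured in pancreas of wild-type (WT) mice and of mice lacking the microRNA miR146a (KO), each given either cerulein, a cholecystokinin analogue whose overdose brings on acute pancreatitis in mice, or phosphate-buffered saline (PBS). The 20 labelled samples fall into 4 groups of 5, WT PBS, WT cerulein, KO PBS and KO cerulein, and the group and replicate number of each were taken from its title. Per the labels' protocols, the mice were littermates 6 to 8 weeks old, injections were given hourly 7 times at 50 µg/kg of cerulein, tissue was collected 1 h after the last, and stranded polyA libraries were read in pairs of 98 bases on an MGI DNBSEQ instrument. The labels name no sex, litter, cage or library batch, so none of these could be entered in a model as stated.

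The authors deposited 1 table of raw whole-number counts per gene and library, with 57126 rows and 1 column for each of the 20 libraries, matched to samples by the library name in the labels. Per the submitters' processing notes, fastp, STAR and the mouse build GRCm39 were used; their versions, the counting tool, its strand setting and the annotation are not given in the sources used here. The file does not pair its rows with gene identifiers or names, and no name was assigned from the order of rows. Genes are therefore written as the number of their row in the table, counted from 1 below the header, and at most 2 that rose and 2 that fell are given. For the same reason, the miR146a locus, the inflammasome and NF-kB genes in the title of the study and the 42 gene lists fixed beforehand were not analysed here, and neither was the test of miR-146a seed sites. How the authors' counting treated paralogs and overlapping genes is unknown, so any single gene may share reads with another.

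The column of WT cerulein replicate 2 held 0 in every row. It was left out, which leaves 19 libraries: 5 WT PBS, 4 WT cerulein, 5 KO PBS and 5 KO cerulein. Of the rows, 28615 held 0 in all libraries. Totals per library ran from 806076 to 36347215 counts, and 4 libraries lay under 2000000 counts: WT PBS replicates 1 and 2 and KO PBS replicates 1 and 2. Depth therefore limits the PBS groups most. Reads carry no molecular identifiers in the deposited counts, so limits set by counting cover counting error only.

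Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum of 10 counts and total of 15, which left 15831. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 19 libraries, so that all groups share the estimates of spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The 5 comparisons were cerulein against PBS in WT, the same in KO, KO against WT after cerulein, KO against WT after PBS, and the genotype by treatment interaction, which is the KO response minus the WT response. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values were computed with the cpm function of edgeR on the scaled library sizes. Where all libraries of a group were at 0, a fold was given as a bound against 3 counts over the whole group, the lower of that from the mean CPM of the other group and that from its pooled counts, since a fitted fold then depends on the prior count.

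The procedure was tested on simulated data before it was applied: negative binomial counts were drawn for the 15831 genes from their own means, library sizes and dispersions, with 200 genes changed, 50 at each size. For cerulein in WT, the test recovered 0% of genes changed 2-fold, 28% of those changed 4-fold, 44% at 8-fold and 60% at 16-fold, with 3 false calls. For cerulein in KO, the shares were 10%, 38%, 44% and 60%, with 0 false calls. For KO against WT after cerulein they were 2%, 20%, 66% and 66%, with 1 false call, and for KO against WT after PBS 6%, 36%, 46% and 56%, with 4. Most 2-fold differences were thus not detected in these draws. Each gene was drawn with 1 dispersion for all groups. The real PBS groups varied more (median SD of log2 CPM 1.12 in WT, 1.07 in KO) than the cerulein groups (0.52 and 0.59). The shares may therefore be too high for KO against WT after PBS and too low after cerulein.

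The digestive enzyme share could not be formed without gene names. In its place, the share of counts in the genes that each hold over 1% of the counts of all libraries together was used; there were 15 such genes, and groups were compared by an exact two-sided permutation test of the difference in means. The responses of the genotypes were compared by Pearson and Spearman correlation across genes, which are not independent replicates, so no p is given.

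The rule for named genes was fixed before the data were examined: among genes called, with a mean CPM of at least 5 in the higher group and ranges that do not overlap between the compared groups, those with the largest positive and negative log2 fold change. With no names, it was applied to cerulein in WT and shortened to the first in each direction. The rule also excluded some kinds of gene by symbol, such as pseudogenes and immunoglobulin segments, which could not be done here. The genes called in the PBS and interaction comparisons were added, since the rule let all genes with a name be given where a comparison has few calls. These genes have no name here, so the addition was made after their values were seen.

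Alternatives planned before the data were examined were RLE scaling, no filter or a filter of CPM above 1 in at least 5 libraries, a minimum absolute log2 fold change of 1, the replicate number as a block, 1 surrogate variable (sva 3.50.0), limma 3.58.1 with voom and sample quality weights, DESeq2 1.42.0, a fit of only the groups compared, and leaving out each library in turn. Others were added afterwards. Replicates were compared within groups before averaging: a chi-square of the counts of the closest pair in each group, over genes with a sum of at least 20, was 18.6 to 84.6 per degree of freedom, so no pair agreed within sampling noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.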

Results

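To profile which genes respond to experimental acute pancreatitis with and without miR146a, pancreas transcriptomes of WT and KO littermates given cerulein or PBS were compared. Counts were available for 5 WT PBS, 4 WT cerulein, 5 KO PBS and 5 KO cerulein mice. Genes are given by row number because the deposited table does not pair its rows with names. The questions that rest on named genes, including the levels of miR146a itself in the KO mice, were not analysed here.

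Depth differed widely between libraries. Totals were 893520, 1257890, 8681076, 2117078 and 8813134 counts in WT PBS replicates 1 to 5, and 6363147, 15725084, 4880131 and 15479938 in WT cerulein replicates 1, 3, 4 and 5. In KO they were 806076, 1707961, 4496212, 36347215 and 9215620 after PBS and 23746372, 11222046, 18802683, 35155403 and 8510924 after cerulein. Between 11388 genes, in KO PBS replicate 1, and 23354, in KO cerulein replicate 1, had at least 1 count.

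A small set of very abundant transcripts filled much of most libraries, but little of some. The 15 genes above 1% of all counts together held 38.7% of them. Their share was 22.7% ± 18.6 (SD, n = 5) in WT PBS, 40.4% ± 4.06 (SD, n = 4) in WT cerulein, 42.5% ± 16.6 (SD, n = 5) in KO PBS and 36.1% ± 11.3 (SD, n = 5) in KO cerulein. In exact two-sided permutation tests, no difference between groups reached p under 0.05. Cerulein gave 17.7 percentage points in WT (exact permutation p = 0.119) and -6.45 points in KO (exact permutation p = 0.492). KO against WT gave -4.34 points after cerulein (exact permutation p = 0.468) and 19.8 points after PBS (exact permutation p = 0.119). With so few mice per group, this does not show that the shares are alike. After adjustment over these 4 tests, p was 0.238, 0.492, 0.492 and 0.238 in the same order. Leaving out WT PBS replicate 3, at 49.7%, brought the WT cerulein difference to 24.5 points (exact permutation p = 0.0286) and the PBS difference between genotypes to 26.6 points (exact permutation p = 0.0476). Leaving out WT PBS replicate 4, at 2.15%, brought them to 12.6 points (exact permutation p = 0.229) and 14.7 points (exact permutation p = 0.214). Leaving out KO PBS replicate 1, at 14.2%, brought the PBS difference to 26.9 points (exact permutation p = 0.0476).

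**Figure D1:**
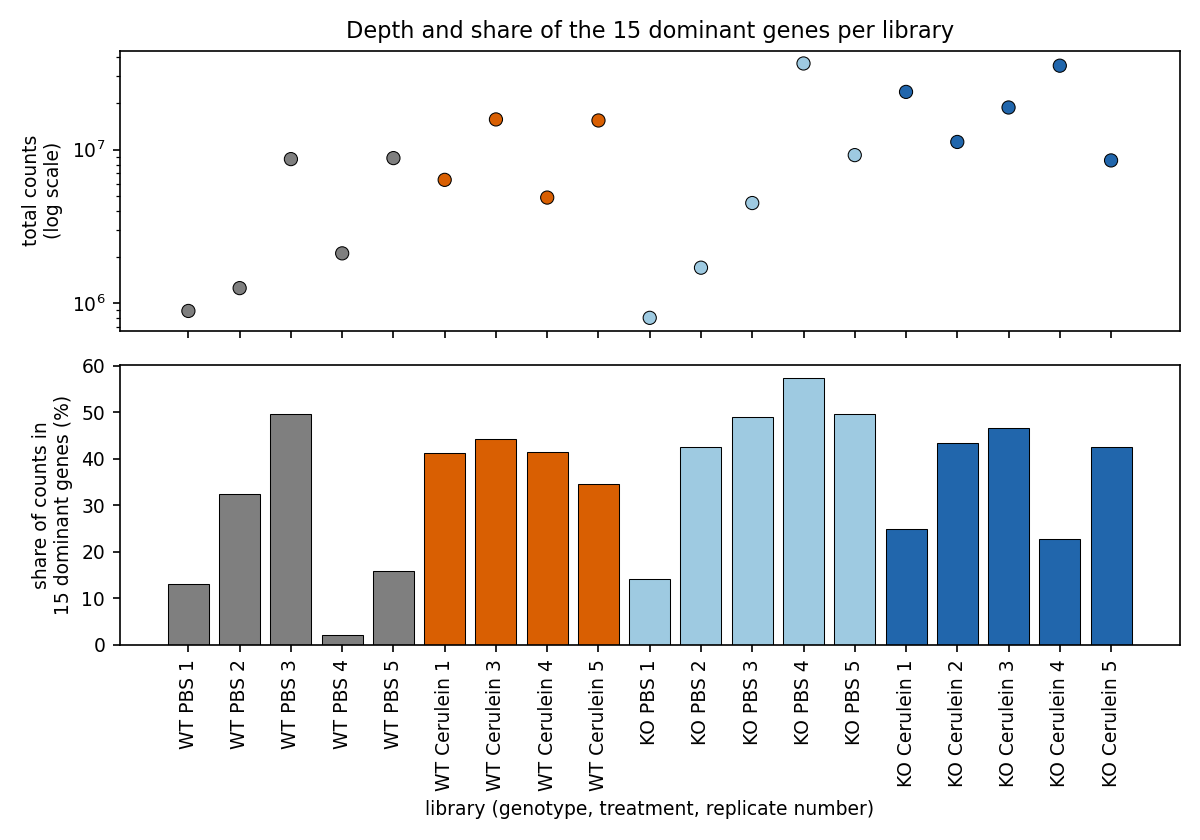
Total counts (upper panel, log axis) and the percentage of counts in the 15 dominant genes (lower panel) for each of the 19 libraries, coloured by group. Totals run from 806076 to 36347215, and the dominant share runs from 2.15% in WT PBS replicate 4 to 57.2% in KO PBS replicate 4.

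Cerulein libraries resembled one another more than PBS libraries did. The mean Spearman correlation of log2 CPM between libraries of a group, across the 15831 tested genes, was 0.921 over 6 pairs in WT cerulein and 0.893 over 10 pairs in KO cerulein, against 0.772 and 0.802 over 10 pairs each in WT PBS and KO PBS. The median SD of a gene's log2 CPM was 0.52 in WT cerulein (n = 4) and 0.59 in KO cerulein (n = 5), and 1.12 and 1.07 in WT PBS and KO PBS (n = 5 each). The PBS groups were also shallower, with median totals of 2117078 (WT) and 4496212 (KO) counts. The medians after cerulein were 10921542.5 (WT) and 18802683 (KO). How much of the difference in likeness comes from depth was not tested. WT PBS replicate 4 was closer to KO cerulein replicates 1 and 4 (rho 0.895 and 0.890) than to any library of its own group (0.683 to 0.807). KO cerulein replicates 1 and 4 reached 0.972 with each other.

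**Figure D2:**
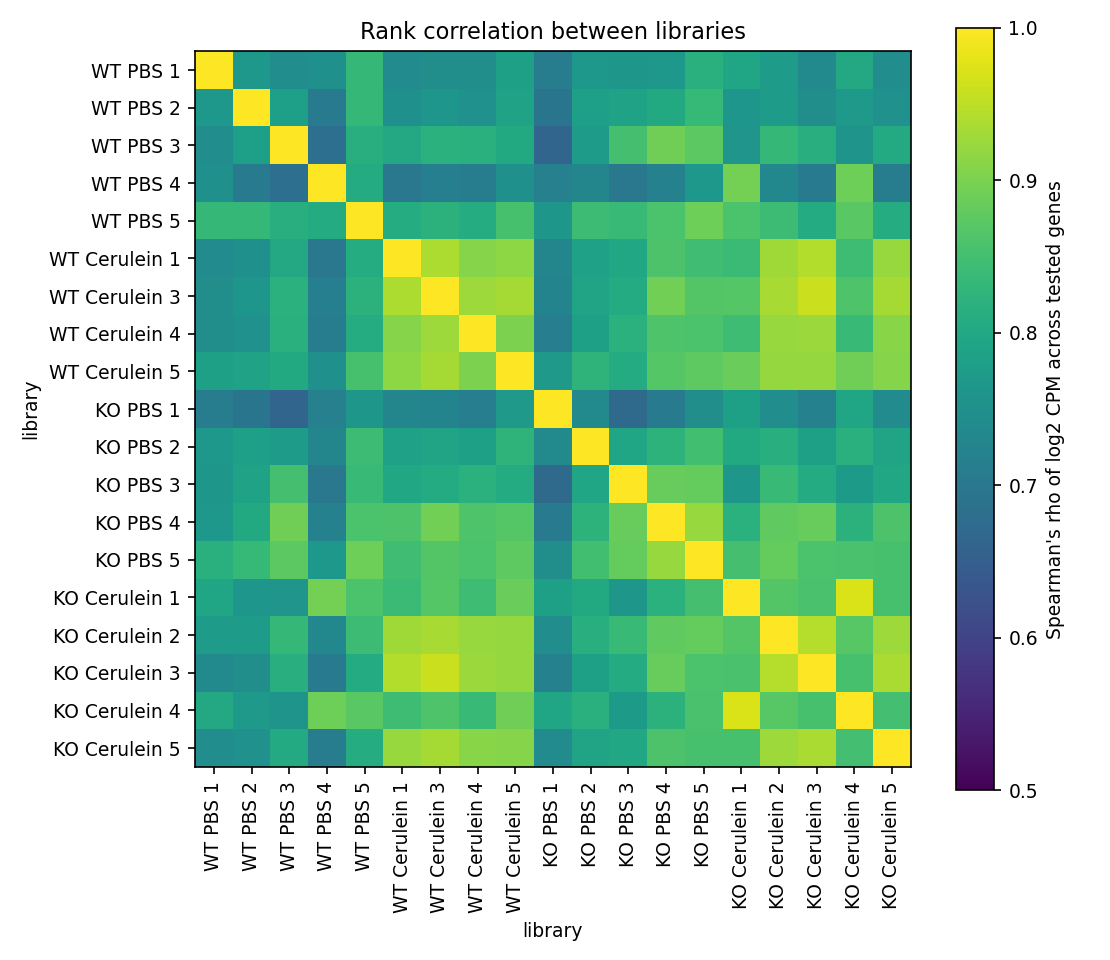
Spearman correlation of log2 CPM across 15831 tested genes between each pair of the 19 libraries, as colour from 0.5 to 1. WT PBS replicate 4 correlates at 0.895 and 0.890 with KO cerulein replicates 1 and 4, and KO PBS replicate 1 has the lowest value, 0.664, with WT PBS replicate 3.

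In WT mice, cerulein changed 889 genes, of which 676 rose and 213 fell (edgeR quasi-likelihood test, adjusted p under 0.05). The median rise was 3.58-fold (log2 1.84, interquartile range 1.32 to 2.88) and the median log2 change of the genes that fell was -1.89 (interquartile range -2.99 to -1.37). Changes above 8-fold were seen for 161 genes that rose and 53 that fell. The largest rise among genes that met the naming rule was in row 17248, with 0 counts in all 5 PBS libraries and 95.4 CPM ± 3.98 (SD, n = 4) after cerulein, at least 831-fold higher (edgeR adjusted p = 6.99e-07; higher in 4 of 4 libraries); without PBS replicate 5, the deepest of its group, the bound was 405-fold. The largest fall was in row 18049, from 91.8 CPM ± 135 (SD, n = 5) to 0 counts in 4 of 4 cerulein libraries, at least 637-fold lower (edgeR adjusted p = 0.0118). The PBS mean of row 18049 was carried by replicate 1 at 332 CPM; the other 4 libraries lay between 18.7 and 37.0 CPM, and without replicate 1 the bound was also 405-fold. It was 372-fold without WT cerulein replicate 5. Bounds of this kind could be lower if several reads were copied from each starting molecule. Libraries of the 2 treatments did not overlap for 1386 genes that were higher and 504 that were lower after cerulein, where chance gives 126 each (0.794% of genes).

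The count in WT fell without any 1 of the cerulein libraries, to 443, 378, 570 or 618 without replicate 1, 3, 4 or 5. Leaving out a library lowers n, and these fits tested more genes (16621 to 16695). With all libraries, the WT count was 1847 with DESeq2 (899 higher, 948 lower) and 1959 with limma-voom. RLE scaling moved the balance to 558 higher and 308 lower.

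In KO mice, cerulein changed 297 genes, 214 upwards and 83 downwards. The median rise was 3.68-fold (log2 1.88, interquartile range 1.43 to 2.76), the median log2 change of those that fell was -1.84 (interquartile range -2.77 to -1.47), and 44 rose and 15 fell by over 8-fold. Row 17248 rose here too, from 0.258 CPM ± 0.440 (SD, n = 5; 12 counts over the group) to 59.8 CPM ± 30.2 (SD, n = 5), a log2 fold change of 7.25 (SE 0.63, edgeR adjusted p = 5.92e-06; higher in 5 of 5 libraries). The change was 8.31 without KO PBS replicate 5, which held 7 of the 12 counts. Row 18049 did not pass the test in KO (log2 fold change 2.30, SE 1.45, edgeR adjusted p = 0.521), with 6.32 CPM ± 12.0 (SD, n = 5) after PBS and 24.9 CPM ± 26.4 (SD, n = 5) after cerulein. PBS replicate 1, at 27.7 CPM, carried the first mean (0.976 without it), and cerulein replicates 1 and 4, which stand apart, at 37.3 and 62.3 CPM, carried the second (8.33 without them, 2 of the other 3 being at 0). Its difference between the responses did not pass either (interaction adjusted p = 0.263 with edgeR). Libraries did not overlap for 723 genes that were higher and 243 that were lower, where chance gives 62.8 each (0.397% of genes).

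The KO count moved with single libraries as well, to 539 without KO PBS replicate 1, 193 without KO PBS replicate 3, and 144 and 168 without KO cerulein replicates 3 and 5. It was 699 without the 4 libraries under 2000000 counts, 540 without the 3 libraries that stand apart (WT PBS replicate 4, KO cerulein replicates 1 and 4) and 1275 without both sets. With DESeq2 it was 872 (436 higher, 436 lower), with limma-voom 1522, and RLE scaling gave 179 higher and 114 lower.

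**Figure D3:**
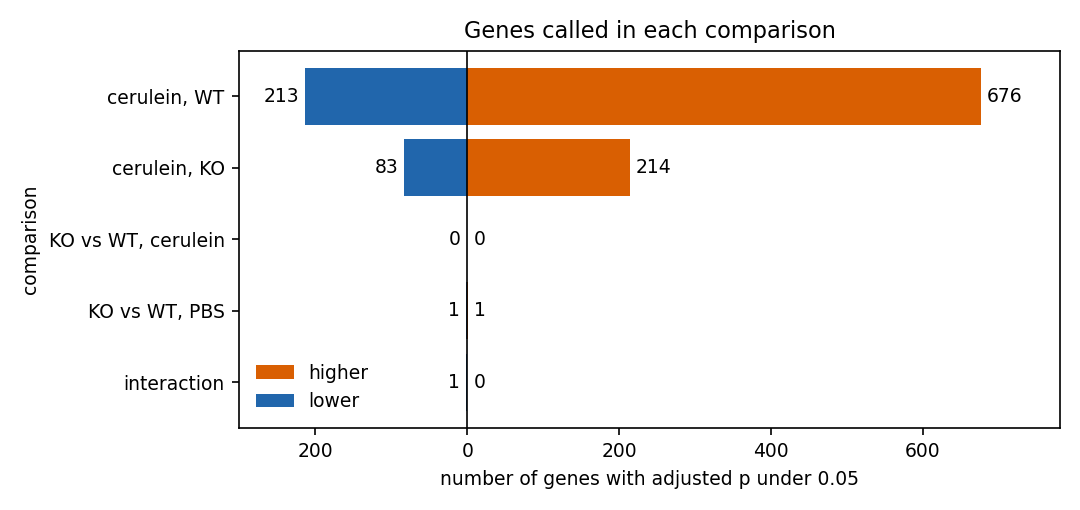
Number of genes with an edgeR adjusted p under 0.05 in each of the 5 comparisons, higher to the right and lower to the left of 0. Cerulein changed 889 genes in WT and 297 in KO, whereas the comparisons between genotypes gave 0, 2 and 1.

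Genes called in both genotypes moved the same way. Of the 676 and 214 genes that rose, 166 were shared, where independent lists would share 9.14; of the 213 and 83 that fell, 36 were shared, against 1.12; and 0 of the shared genes had opposite signs. The WT and KO responses have no libraries in common, but both come from 1 joint fit that shares each gene's estimate of spread. The values for independent lists take all tested genes as equally likely to be called, so they may be too low. Across all 15831 genes, the log2 fold changes of the genotypes correlated at Pearson 0.209 and Spearman 0.293, with the same sign for 61.8%. Over the 984 genes called in either genotype the values were 0.624, 0.728 and 92.6%. Without the 3 libraries that stand apart, the correlation over all genes was 0.477 (Spearman 0.537). Across both genotypes, 33 genes were at least 2-fold higher in each of the 9 cerulein libraries than in any of the 10 PBS libraries; with no margin, 233 genes lay above and 22 below, where chance gives 0.171 each.

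Between KO and WT mice given cerulein, 0 genes passed the adjusted threshold with edgeR, and 650 had an unadjusted p under 0.05, where 792 are expected with no difference. That number depended on the fit. With only the groups compared it was 928 of 15081 tested genes, above the 0.05 share expected, and the adjusted count stayed at 0. Without the 3 libraries that stand apart it was 272 of 15797. DESeq2 called 21 genes, all 21 higher in KO, and limma-voom 2. Non-overlapping libraries were seen for 202 genes that were higher in KO and 127 that were lower, where chance gives 126 each. Row 17248, at 59.8 CPM ± 30.2 (SD, n = 5) in KO and 95.4 CPM ± 3.98 (SD, n = 4) in WT, had a log2 difference of -0.68 (SE 0.45, edgeR adjusted p = 1). KO replicates 1 and 4, which stand apart, lay at 26.1 and 29.7 CPM, and the other 3 between 68.8 and 90.3 CPM. Leaving out any 1 library left the edgeR count at 0.

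After PBS, 2 genes differed between KO and WT. The gene in row 43726 was at 117 CPM ± 94.9 (SD, n = 5) in KO and 2.50 CPM ± 1.31 (SD, n = 5) in WT, a log2 difference of 5.63 (SE 0.53, 49.5-fold, edgeR adjusted p = 7.84e-06; higher in 5 of 5 libraries). Without KO PBS replicate 1, at 284 CPM against at most 100 in the others, the log2 difference was 5.01. In row 33693 the gene had 0 counts in all 5 KO libraries and 23.5 CPM ± 24.8 (SD, n = 5) in WT, at least 245-fold lower in KO (edgeR adjusted p = 0.0136). The WT mean was raised by replicate 4, which stands apart, at 65.1 CPM; the other 4 lay between 1.94 and 23.1 CPM, and without it the bound was 136-fold. Without KO PBS replicate 4, the deepest library, it was 104-fold. An unadjusted p under 0.05 was seen for 1401 genes, where 792 are expected. With only the groups compared it was 478 of 11777 tested genes, below the 0.05 share expected, so this excess was not seen there. Non-overlapping libraries were seen for 76 genes that were higher in KO and 66 that were lower, where chance gives 62.8 each. DESeq2 called 85 genes and limma-voom 6, and limma-voom did not call either of these 2 (adjusted p 0.117 for row 43726 and 0.0553 for row 33693). Without WT PBS replicate 3 the edgeR count was 12; without WT PBS replicate 5, KO PBS replicate 1 or KO PBS replicate 2 it was 4; and without KO PBS replicate 3, 4 or 5 it was 1, the call for row 33693 being lost (adjusted p 0.0517, 0.106 and 0.0683; bounds 219, 104 and 192-fold). Row 33693 also lost its call without the 4 libraries under 2000000 counts (edgeR adjusted p = 0.0592, bound 253-fold) and with counts divided by their most frequent value from 5 up (edgeR adjusted p = 0.158). With only the groups compared, the single gene called was row 43726 (edgeR adjusted p = 0.00208). Row 33693 had no test result in that fit, so its call was neither kept nor lost there.

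The interaction was significant for 1 gene, again row 43726. It rose with cerulein in WT, from 2.50 CPM ± 1.31 (SD, n = 5) to 152 CPM ± 54.6 (SD, n = 4; log2 fold change 6.01, SE 0.55, edgeR adjusted p = 1.23e-06), and lay at 117 CPM ± 94.9 and 103 CPM ± 43.8 (SD, n = 5 each) in KO after PBS and cerulein (log2 fold change -0.18, SE 0.41, edgeR adjusted p = 0.910). The difference between the responses was -6.19 on the log2 scale (SE 0.67, edgeR adjusted p = 9.14e-05), and -5.57 without KO PBS replicate 1. These comparisons share the WT PBS libraries, in which the gene lay between 1.06 and 4.61 CPM. Row 33693 rose with cerulein in KO, from 0 counts in 5 libraries to 14.7 CPM ± 13.3 (SD, n = 5), at least 154-fold (edgeR adjusted p = 0.00198), and its interaction did not pass (edgeR adjusted p = 0.0711). That mean was carried by KO cerulein replicates 1 and 4, which stand apart, at 31.6 and 26.4 CPM; the other 3 lay between 2.36 and 7.00 CPM, for which the bound was 48.1-fold. Without KO PBS replicate 4 it was 64.9-fold. DESeq2 called 104 genes for the interaction and limma-voom 2, without row 43726 (adjusted p = 0.115), and without any filter edgeR called 13. Without WT PBS replicate 3 the edgeR count was 4, and without WT PBS replicate 2 or 5, WT cerulein replicate 3, KO PBS replicate 1 or 2, or KO cerulein replicate 3 it was 2.

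**Figure D4:**
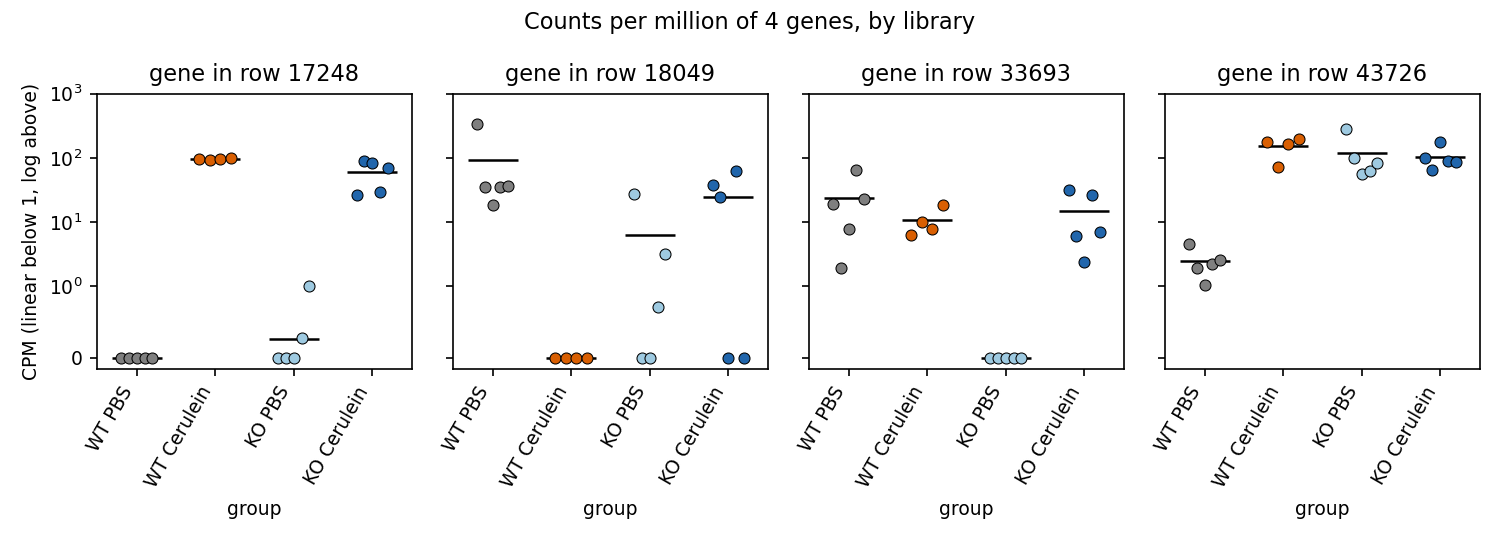
CPM of the genes in rows 17248, 18049, 33693 and 43726 in each library, by group, on an axis that is linear below 1 and logarithmic above; horizontal lines are group means. Row 43726 lies between 1.06 and 4.61 CPM in WT PBS and at 56.5 CPM or more in all other libraries, and row 33693 is at 0 counts in the 5 KO PBS libraries.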

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

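The tests of the 3 patterns below were chosen after the results were seen, and those of the first pattern and of low depth replaced earlier tests, whose values are also given; the regroupings of libraries were planned before the data were examined. A single library stood far from the rest of its group in 5 of 37 sets of values examined, where chance gives 1.85. KO PBS replicate 4 had 36347215 counts, against 806076 to 9215620 in the other 4. The gene in row 17248 had 1.01 CPM in KO PBS replicate 5, from 7 counts, against at most 0.275. Row 18049 had 332 CPM in WT PBS replicate 1, against at most 37.0, and 27.7 CPM in KO PBS replicate 1, against at most 3.19. Row 43726 had 284 CPM in KO PBS replicate 1, against at most 100. The response of this gene also differed between genotypes, by -6.19 on the log2 scale in the interaction test.

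In 100 regroupings of the libraries, the real one included, only the real one reached its count of genes changed by cerulein, in WT and in KO. The count was 889 in WT (1 of 100 splits, highest other 841) and 297 in KO (1 of 100, highest other 20). Chance is thus unlikely for both, at 1 in 100, the smallest share that these splits can give. It could not be excluded for KO against WT after PBS (2; 8 of 100, highest other 643) or for the interaction (1; 6 of 100, highest other 698). For KO against WT after cerulein the splits decide nothing, since a count of 0 is reached by all 100 (highest other 1). The WT split with 841 genes put PBS replicate 3 with all 4 cerulein libraries. The PBS split with 643 put WT replicate 3 with KO replicates 2 to 5 and KO replicate 1 with the other WT libraries.

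The first pattern is the lower count of cerulein genes in KO (297) than in WT (889), for which neither explanation tested could be settled. Spread added by shallow libraries and by libraries that stand apart stays open: of 1779 genes called for cerulein averaged over genotypes, with each genotype fitted alone, the median SE of the KO response (1671 genes) was 0.951 times that of the WT response (1659 genes; leave-one-out 0.833 to 1.06), and 0.937 in the joint fit, which shares the spread between groups. Leaving out those 7 libraries moved the counts to 1275 in KO and 1111 in WT in the joint fit, and from 340 and 730 to 1718 and 596 in the separate fits, but leaving out only the 3 that stand apart gave 318 and 1021 there, with an SE ratio of 1.10. Leaving out only the 4 shallow libraries gave 1014 in KO and 442 in WT in the separate fits, with an SE ratio of 0.898. A smaller response to cerulein in KO mice stays open too: over these genes (1772 to 1779 tested in each set of libraries), the KO minus WT change in the direction of the response had a median of -0.34 log2 with all libraries (leave-one-out -0.46 to -0.25), -0.25 without the 4 shallow libraries, -0.17 without the 3 that stand apart and -0.093 without both (leave-one-out -0.20 to 0.01). With the genes chosen again in the last subset (2945 genes), which keeps only WT PBS replicates 3 and 5 and is too small to decide, the median was -0.03 (leave-one-out -0.10 to 0.08).

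The second pattern is the 3 libraries that stand apart, WT PBS replicate 4 and KO cerulein replicates 1 and 4. Exchanged treatment labels were excluded: over 104 genes at least 2-fold higher in every other cerulein library than in every other PBS library, with the PBS mean set to 0 and the cerulein mean to 1, KO cerulein replicates 1 and 4 had median positions of 0.675 and 0.634 and WT PBS replicate 4 of -0.0818. RNA of another tissue or cell population in these libraries is a candidate explanation that stays open: of the genes at least 4-fold away from the other libraries of their treatment in all 3, 624 were higher and 2 lower (99.7% higher), as mixing would give. This count leans towards gains, since a gene with few counts can rise 4-fold but has little room to fall 4-fold. It therefore cannot tell mixing from a change of state in these mice. The 15 dominant genes had median changes of -5.95 log2 in WT PBS replicate 4 and -1.48 and -1.50 in KO cerulein replicates 1 and 4. Their ranges were -6.49 to -2.49, -1.78 to 0.44 and -1.76 to -1.13 in that order, so they did not all move by 1 factor. Without gene names no source could be named, and a difference in the state of these mice remains untested.

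The third pattern is a gap at low counts: in KO PBS replicate 1, 309 genes had 1 count and 219 had 2, but 335 had 7, and 9 of 18 libraries had more genes at 7 counts than at 2. Low depth alone was argued against, because the deepest library thinned to each total had more genes at 2 counts than the real library in all 18 cases (485 to 1266 against 201 to 582) and in 0 cases more at 7 than at 2; the ratio of genes at 7 to genes at 2 exceeded the thinned one by over 0.2 in 15, where the earlier test asked for 17. Several reads copied from each starting molecule might give such a gap, but this could not be decided. Detected genes were closer to those of the deepest library thinned to the total divided by the most frequent count from 5 up in 7 of 18 libraries. In several libraries, such as KO cerulein replicate 1, that count was 5, the lower limit of the search. There the divisor may be set by the limit, which weakens the test. Fewer genes were detected than in the deepest library thinned to the full total in 16 of 18. The deepest library may itself hold copied reads, so it is no sure reference. More genes at 7 than at 2 counts were seen in 6 of 10 PBS and 3 of 9 cerulein libraries (Fisher's exact test, two-sided, p = 0.370), and no biological explanation was tested.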

How the results depend on the processing

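The alternatives without the 4 libraries under 2000000 counts, without the 3 libraries that stand apart, without both sets, with counts divided by their most frequent value from 5 up, with a covariate for the on-off genes and with scaling without the 15 dominant genes were chosen after the data were seen. The causes of the shifts below were not tested, except that leaving out libraries lowers n.

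Limma-voom called 1959 genes for cerulein in WT (1357 higher, 602 lower), 1522 in KO (839 and 683), 2 for KO against WT after cerulein, 6 after PBS and 2 for the interaction; DESeq2 called 1847 (899 and 948), 872 (436 and 436), 21, 85 and 104, against 889, 297, 0, 2 and 1 with edgeR. The interaction count was 13 with no filter and 2 with 1 surrogate variable; the PBS count was 1 with only the groups compared. RLE scaling changed the split of calls from 676 higher and 213 lower to 558 and 308 in WT, and from 214 and 83 to 179 and 114 in KO, as it moved the median log2 fold change of all genes from -0.10 to -0.20 in WT and from 0.06 to -0.03 in KO. The KO count was 699 without the libraries under 2000000 counts, 540 without the 3 that stand apart and 1275 without both, where the PBS count was 8. With counts divided by their most frequent value, the counts were 1481 in WT, 852 in KO and 2 for the interaction. The other alternatives kept each count within 1.5 times.

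Leaving out each library in turn gave 378 to 1167 genes in WT, 144 to 539 in KO, 0 to 0 for KO against WT after cerulein, 1 to 12 after PBS and 1 to 4 for the interaction. The correlation of the responses, 0.209, was 0.624 over genes called in either genotype, 0.477 without the 3 libraries that stand apart, 0.387 without both sets, and 0.124 to 0.351 when leaving out each library. When leaving out each library, the dominant-gene share differed by 12.6 to 24.5 points for cerulein in WT and -13.5 to -2.77 in KO. For KO against WT it differed by -6.99 to -1.01 after cerulein and 14.7 to 26.9 after PBS. With the 20 most abundant genes of each library instead, the differences were 13.4, -9.91, -4.95 and 18.4 points in that order. With only the tested genes as denominator they were 17.7, -6.46, -4.32 and 19.8 points. Of the single-gene values, 188 kept direction and side of the threshold and 8 lost the call with the same direction, those of rows 33693 and 43726 in the genotype comparisons. The fit of only the PBS groups, which gave no test result for row 33693, is not among these 8.

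With the replicate number as a replicate block, counts were 747, 250, 0, 2 and 1, and no count moved by over 1.5 times. The numbers were not found to pair the mice: of 27 same-numbered pairs across groups, 5 had a correlation of deviations over 0.1 (range -0.203 to 0.421), and 5 of 19 libraries correlated best with their own number. Not run, because the table carries no gene names: the gene list tests, the seed-site test, the digestive enzyme list in the share and in the scaling, and sex inferred from genes as a covariate. Depth limits the PBS groups most, with totals down to 806076 counts.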

Other observations

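The tests in this part were chosen after the results were seen. A further split of the libraries did not follow the groups. With a covariate for it, 5 genes were either on or off: 4 were on in 9 libraries and nearly absent in the other 10, and 1 was the reverse, at 633 CPM ± 138 (SD, n = 10) against 3.23 CPM ± 6.48 (SD, n = 9). The 9 libraries were WT PBS replicates 1, 2 and 3, WT cerulein replicates 3, 4 and 5, KO PBS replicate 5 and KO cerulein replicates 1 and 5. That is 6 of 9 WT and 3 of 10 KO libraries (Fisher's exact test, two-sided, p = 0.179). With this split as a covariate the counts of calls were 803, 325, 0, 2 and 1 in the order WT, KO, after cerulein, after PBS and interaction, against 889, 297, 0, 2 and 1. What the split stands for was not tested, as the rows carry no names.

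The genotype differences after PBS and after cerulein, which share no libraries, were weakly and negatively related: across 15831 genes their log2 differences correlated at Pearson -0.244 and Spearman -0.215, with the same sign for 41.8%. Without WT PBS replicate 4 and KO cerulein replicates 1 and 4 the values were 0.0324, 0.0646 and 52.8% across 15797 genes. The negative relation thus rested on those 3 libraries.

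Genes that rose with cerulein in WT lay next to each other in the table more often than random lists of the same size. Among the 676, 57 adjacent pairs of tested genes were seen, against a mean of 28.9 and a maximum of 48 in 10000 random lists (permutation p = 1e-04, the smallest these lists can give). Among the 214 that rose in KO, 6 pairs were seen against a mean of 2.88 (permutation p = 0.069). The order of the table's rows was not used to name any gene.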
